A study of Mus musculus with 189 samples.

How the data were processed

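The study used mouse embryonic stem cells (ESCs) of the E14 background grown in serum with LIF, the cytokine that keeps ESCs undifferentiated. Double knockout (DKO) lines lacked Dppa2 and Dppa4, a pair of chromatin-associated DNA-binding proteins of early embryos and ESCs. Per the labels, DKO clones 36, 43 and 53 were compared with wild-type (WT) clones 57 and 58 and the parental line Mc3. Other experiments followed DKO clone 43 and WT clone 58 as embryoid bodies (aggregates that differentiate without LIF) on days 1, 2, 3, 4, 7 and 9, overexpressed Dppa2 or Dppa4 as GFP fusions, or induced short hairpin RNAs against either gene with doxycycline. Of 189 samples, 165 had values analysed here. Targeted bisulfite amplicons and 6 inputs of the DKO and WT chromatin libraries were not analysed here.

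The authors deposited RNA values as log2 RPM (reads on a gene scaled to the library's mapped reads) for each of 25965 gene models. Chromatin values for DKO and WT cells were deposited as log2 RPM in windows of 1000 bases, 2725549 in all, and those of the hairpin lines as linear RPM in the same windows. In 1 hairpin column (H3K27me3, Dppa4 hairpin without doxycycline, replicate 1) the deposited signal was taken to be on the same scale, although an automatic test for whole reads did not accept its step per read. In the log2 tables, values without reads held the log2 of 0.9 read expressed as RPM, a floor that was recognised from the values. It was set to 0 RPM for RNA but kept in the promoter values of DKO and WT cells. CpG methylation was deposited as percent methylation per window, with a median window length of 13783 bases and no coverage column, so the depth behind a methylation value is unknown. It came from NOMe-seq, per the series labels, an assay that also marks accessible GpC sites with an enzyme. The submitters' processing notes name Trim Galore 0.4.4, 0.5.0, 0.6.1 and 0.6.5, HISAT2 2.1.0, Bowtie2 2.3.2, Bismark 0.18.2, cutadapt 2.3 and the GRCm38 (mm10) build, without saying which step used which. The assay of the 12 libraries analysed as ATAC-seq (a transposase assay of open chromatin) was recognised by elimination among the column names, and whether reads were shifted for the transposase is not given in the sources used here. Read strand, multi-mapping and the handling of near-identical copies are not given either, so values of gene families such as Zscan4, Rhox and Hox are uncertain between members.

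Whole reads could be recovered from the step between low RPM values. In RNA libraries at least 99.52% of values came out whole within a tolerance of 0.01 read, and in chromatin libraries 100%. Mapped reads, in mega-reads (M), were 5.29 to 8.582 M in ESC RNA libraries, 6.687 to 49.65 M in embryoid bodies, 8.657 to 10.51 M in overexpression clones, 21.52 to 28.96 M for H3K4me3 and 18.5 to 22.1 M for H3K27me3 in DKO and WT cells, and 12.05 to 44.96 M for ATAC-seq. Hairpin libraries had 7.173 to 10.83 M for H3K4me3 and 5.857 to 12.71 M for H3K27me3. EZH2, RING1B, H2A.Z and Ash2l had 1 library each from clones 43 and 58, at 15.1 to 20.39 M.

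A second ESC table, carrying polyA RNA labels, held the same values as the total RNA table in all 17 libraries they share (0 of 25965 genes differed). It was therefore not used as a second measurement, and the tests of polyA RNA and of the overlap between both library types were not run. Its additional library, B of clone 43, held 823345 reads on genes and entered only an added alternative.

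RNA was tested with limma 3.58.1 (eBayes with trend) in R 4.3.3 on log2(RPM + 1), with Benjamini-Hochberg adjustment and a threshold of 0.05 (two-sided). Fold changes are on the log2(RPM + 1) scale, which understates the change of low genes. Genes needed a mean of at least 0.5 RPM, which left 13403 genes in ESCs, 14264 in overexpression clones and 14109 in embryoid bodies. Clone was the replicate in ESCs (3 against 3, libraries of a clone averaged) and in overexpression (2 clones per construct in 1 fit of 6 clones). The 36 embryoid body libraries were fitted together, with 3 differentiation sets per day and genotype. Sets repeat the differentiation, not the clone, so genotype and clone cannot be told apart there. The labels do not say that the hairpin replicates were separate cultures, so their p-values measure only the spread between these samples.

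A promoter was the mean log2 RPM (pseudocount 1 for linear values) of the windows that overlapped 1000 bases either side of a gene's 5' end, which took 3 windows. The linear values are those of the hairpin lines, so their changes are on the log2(RPM + 1) scale. That scale understates changes at low signal, and their sizes do not compare with those in DKO cells. Of the gene models, 2705 shared their windows with another. Libraries were aligned by cyclic loess over the tested promoters and tested with limma. Promoters needed a mean of at least 1 log2 above input. Because input columns were in the hairpin table, promoters for both DKO marks were those at least 1 log2 above the hairpin table's 6 inputs in the mean of that mark's 18 libraries, a departure from the design, and this left 13654 for H3K4me3 and 4155 for H3K27me3. ATAC-seq used the 12983 promoters at or above the median. Windows without reads kept the floor, which lies lower in deeper libraries. Mapped reads of this assay were 12.05 to 20.51 M in WT and 17.69 to 44.96 M in DKO libraries. The effect of the floor on the falls was not tested. H3K27me3 had 2 DKO clones (36 and 53). Promoters lower in H3K4me3 in DKO cells formed a set that was read out in the other libraries with limma's camera. With 1 library per group, the set's median was placed among 10000 random lists matched on signal in 20 bins. A bivalent promoter carried H3K4me3 and H3K27me3, both at least 1 log2 above input in the untreated hairpin libraries, and its share was tested with Fisher's exact test, two-sided.

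The 20 gene lists were naive pluripotency, primed or formative pluripotency, 2-cell-like and zygotic genome activation, germline, mesoderm and primitive streak, cardiac, endoderm, neuroectoderm, trophoblast, blood and endothelium, fibroblast and mesenchyme, Hox, COMPASS, Polycomb, DNA methylation machinery, imprinted, p53 response, heat shock and unfolded protein, housekeeping controls, and mitochondrially encoded. They were tested with camera at its preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. Lists, tests and the rule for named genes were chosen before the data were examined. The rule takes Dppa2 and Dppa4 in each RNA comparison. It adds, among genes past the threshold with groups that do not overlap and leaving out Gm, Rik and pseudogene names, the 8 largest rises and falls (in embryoid bodies 8 at day 9 and 4 on other days), and up to 4 members of each list with the smallest adjusted p whether or not they pass. For promoters it takes the 8 largest each way in DKO cells and 4 each way per hairpin contrast, and the 8 H3K4me3 falls are read out in libraries without replicates. A promoter that the rule takes is not reported here.

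Alternatives chosen before the data were examined were a pseudocount of 0.1, no filter, quantile normalization, single libraries with clone as a random effect, the replicate number as a block, promoter values as deposited, 500 bases either side, a stricter bivalent class (2 log2 above input), smaller promoter sets, and leaving out each replicate. Chosen after seeing the data were edgeR 4.0.16 (quasi-likelihood) on the recovered reads, each embryoid body day fitted alone, leaving out ESC libraries with under 80% of reads on genes, adding library B of clone 43, leaving out the library labelled WT of set 2 at day 3, the block in list and promoter set tests, an estimated correlation for the promoter set, and the contrasts of recovery with doxycycline, of both hairpins and of both overexpressed genes.

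Same-numbered libraries were checked for deviations in common from their group means. A comparison was taken as paired or not from the lowest correlation among its same-numbered pairs. The set numbers of embryoid bodies paired on days 2, 4, 7 and 9 (lowest correlation of a pair 0.357, 0.194, 0.217 and 0.275). In the hairpin lines the numbers paired for the Dppa2 hairpin in each contrast (lowest 0.12) and for the Dppa4 hairpin with doxycycline (0.105 for H3K4me3 and 0.107 for H3K27me3). Another measure, whether a library correlated best with its own number, differed. It held for each set on day 1 but not for set 1 on day 7. For H3K27me3 in recovery of the Dppa2 hairpin it held for number 2 alone. The labels of embryoid bodies name the same sets for both clones, while those of the hairpin lines do not say what a number marks. The main fit of embryoid bodies left the set out. Where a block was added, it was 1 effect per number, common to all days or to all 18 libraries of a mark. Such a block does not take up deviations particular to 1 day or contrast. Only where a day was fitted alone did the set as a block pair the libraries of that day. Whether numbers paired was judged from the values.

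The tests were checked on simulated data built from each comparison's own means and spread, with 200 features changed. For ESC RNA (13403 genes) limma recovered 16% of genes changed by a log2 of 1 and 76% of those changed by 2, with 2.02% of calls false, and edgeR 14% and 75%. For overexpression (14264 genes) limma recovered 64% and 91%, with 5.65% of calls false, and for embryoid bodies at day 4 (14109 genes) 54% and 84%, with 7.5% false. For promoters in DKO cells the shares were 76% and 93% for H3K4me3 (13654 promoters), 85% and 97% for H3K27me3 (4155), and 29% and 90% for ATAC-seq (12983), with 3.43%, 6.19% and 3.25% of calls false. In the hairpin lines, changes of 0.5 and 1 were recovered in 88% and 100% for H3K4me3 and in 75% and 100% for H3K27me3, with 6% and 6.91% of calls false. The false share was thus above 5% for overexpression, embryoid bodies, H3K27me3 in DKO cells and both hairpin marks. Each simulation was drawn once, and the threshold bounds the expected share. A single draw therefore cannot show whether the tests exceed it. Extraction and plots used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.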

Results

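RNA, promoter chromatin and CpG methylation were measured in mouse ESCs with and without Dppa2 and Dppa4, and RNA was followed while such cells differentiated as embryoid bodies. ESC RNA came from 9 WT libraries of 3 lines and 8 DKO libraries of 3 lines, with 4487769 to 7748636 reads on genes. Embryoid bodies gave 3 WT and 3 DKO libraries on each of 6 days. Overexpression clones gave 6 libraries each for GFP alone, Dppa2-GFP and Dppa4-GFP. Chromatin of DKO and WT lines was profiled for H3K4me3 (a mark of active promoters, 3 against 3 lines), H3K27me3 (the Polycomb mark, 2 DKO against 3 WT lines) and accessibility (3 against 3 lines, 2 libraries each). Both marks were also profiled in Dppa2 and Dppa4 hairpin lines without doxycycline, after 7 days of it, and after 7 days followed by 14 days without (recovery), with 3 libraries each.

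The targeted genes were read in each library first. In ESCs, Dppa2 stood at 30.2 to 119 RPM in WT libraries and 5.26 to 25.4 RPM in DKO libraries, and Dppa4 at 70.4 to 145 RPM against 13.7 to 50.3 RPM. Dppa2 was lower by a log2 change of -2.19 ± 0.34 (SE, n = 3 lines each; limma adjusted p = 0.0104) and Dppa4 by -2.18 ± 0.273 (limma adjusted p = 0.00245). In embryoid bodies Dppa2 went from 55.8 to 86.5 RPM in WT and 11.3 to 13.2 RPM in DKO libraries on day 1 to 0.967 to 2.77 RPM and 0 to 1.35 RPM on day 9. Dppa4 was 95.4 to 101 RPM in WT and 25 to 28.8 RPM in DKO libraries on day 1, but 6.97 to 12.2 RPM in WT and 13.8 to 15.1 RPM in DKO libraries on day 9. The values count reads anywhere on a gene model and the deleted part is not given in the sources used here, so remaining reads in DKO libraries do not check a label. The library labelled WT of set 2 at day 3 went against its label for Dppa4, with 6.93 RPM beside 52.2 and 49 RPM in the other day 3 WT libraries and 16.7 to 21.3 RPM in DKO libraries, while its Dppa2 (28.8 RPM) lay in the WT range.

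**Figure D1:**
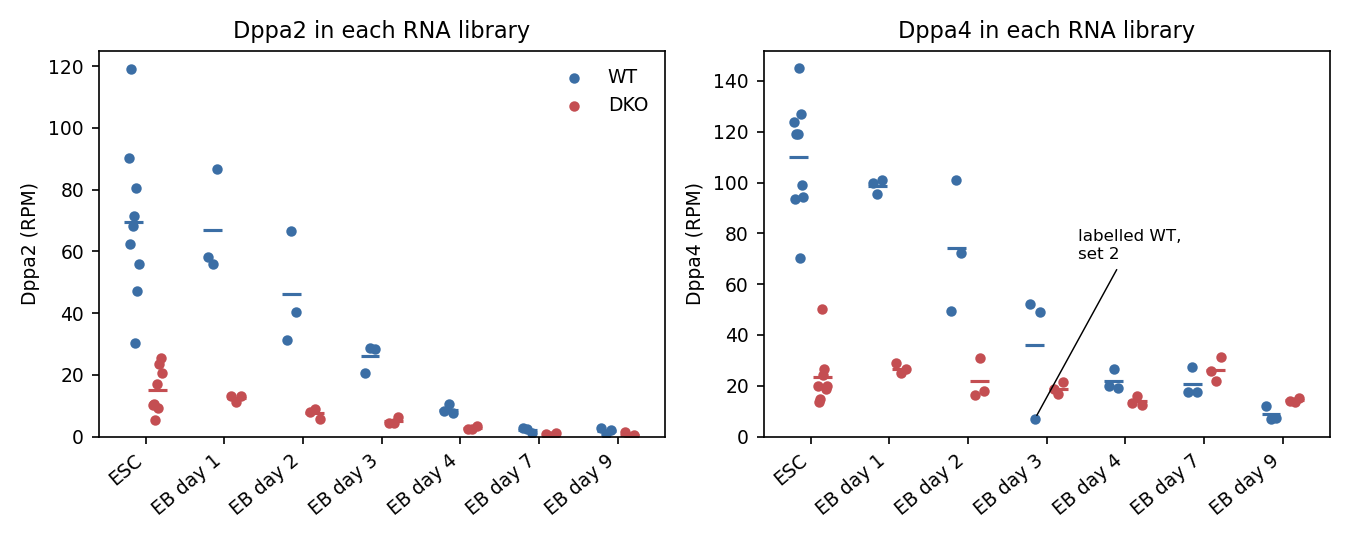
RPM of Dppa2 and Dppa4 (vertical axes) in each library of ESCs and of embryoid bodies by day (horizontal axes), WT in blue and DKO in red, with a bar at each group's mean. The library labelled WT of set 2 at day 3 is marked, at 6.93 RPM of Dppa4.

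In undifferentiated ESCs, loss of Dppa2 and Dppa4 went with lower RNA of germline genes. Ddx4, a germ cell RNA helicase, fell from 13.8 ± 4.8 to 0.0279 ± 0.0242 RPM (SD, n = 3 lines each; log2 change -3.77 ± 0.292 SE, limma adjusted p = 9.68e-05). Mael, of the piRNA pathway, fell from 16.9 ± 11.1 to 0.555 ± 0.495 RPM (-3.31, limma adjusted p = 0.00245), and Dazl, a germ cell RNA-binding protein, from 9.49 ± 5.46 to 0.162 ± 0.191 RPM (-3.01, limma adjusted p = 0.00157). Syce1 of the synaptonemal complex (-3.51) and the X-linked homeobox gene Rhox13 (-2.54) also fell. Sohlh2, a germ cell transcription factor, was listed at 0 RPM in each DKO line and at 3.87 to 21.1 RPM in WT lines. The largest fall was that of Rpl10l, a ribosomal protein paralog used in spermatogenesis, from 53.2 ± 7.94 to 0.769 ± 0.518 RPM (-4.97 ± 0.297, limma adjusted p = 1.37e-05). D1Pas1, a helicase gene of the testis, fell by 3.61 on the log2 scale.

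Of 38 measured germline genes 16 fell, and 22 fell when adjusted over the list alone (median -1.12, camera adjusted p = 5.4e-46). Of 13 measured 2-cell-like genes, which mark cells resembling the embryo at genome activation, 4 fell, and 13 fell adjusted over the list alone (median -1.58, camera adjusted p = 1.92e-25). Both lists had an adjusted p = 0.304 with an estimated correlation. Zscan4d and Gm8300 were listed at 0 RPM in the DKO lines and at 2.13 to 15.8 and 1.76 to 18.4 RPM in WT lines. Single genes of other lists fell too, namely the epithelial keratin Krt19 (37.6 ± 16.3 to 4.08 ± 2.14 RPM, -2.74), the trophoblast-linked Rhox9 (-1.80) and Rhox6 (-1.51), the matrix protease Mmp2 (-1.79), the somite gene Mesp2 (-1.47) and the surface marker Cd34 (-1.32). The naive pluripotency list (median -0.272, 0 of 22 called, camera adjusted p = 9.67e-05) and the Hox list (median -0.274, 0 of 11, adjusted p = 0.00625) were called lower as lists, each with adjusted p = 0.646 with an estimated correlation. The mitochondrially encoded list was lower too (median -0.188, 0 of 10 genes, adjusted p = 0.0144, and adjusted p = 0.646 with an estimated correlation), but its direction turned after quantile normalization (adjusted p = 0.988). WT library C of line 58 had 22.35% of its gene reads from mitochondria, beside 0.564% to 6.167% in the other WT libraries.

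Fewer genes rose in DKO ESCs. Barx1, a homeobox gene of mesenchyme, rose from 0.421 ± 0.174 to 5.79 ± 2.2 RPM (2.12 ± 0.299, limma adjusted p = 0.00553), and Ptrf, which coats caveolae, from 48.3 ± 6.29 to 131 ± 11.8 RPM (1.45). The collagen gene Col1a1 (1.41), the homeobox genes Irx2 (1.43) and Dmbx1 (1.22), the protocadherin Pcdhac1 (1.48) and the steroid dehydrogenase Hsd17b11 (1.15) rose as well. In total 93 of 13403 genes passed the test, 7 higher and 86 lower. The median of all genes was 0.12, and 0.02 after quantile normalization (a shift of -0.105). The count was 42 without WT line Mc3, 177 without WT line 57, 31 without DKO line 36 and 47 without DKO line 53.

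H3K4me3 asked which promoters lost an active mark with Dppa2 and Dppa4. The largest fall was at Twist2, a mesenchymal transcription factor (chromosome 1, 91801461 to 91848028, GRCm38), with a log2 change of -4.65 ± 0.306 (SE, n = 3 lines each; limma adjusted p = 0.000156). Repin1, a zinc finger gene (chromosome 6, 48593883 to 48599082), followed at -4.54, then the kinase gene Aatk (-4.08), D1Pas1 (-4.03), Uggt2 of glycoprotein folding (-3.94), the somatostatin receptor Sstr4 (-3.74), the zinc finger gene Zfp629 (-3.69) and the serotonin receptor Htr4 (-3.66 ± 0.465, limma adjusted p = 0.0019). Rises were smaller, with the RNA-binding protein Celf3 (1.86), the RNA editing enzyme Apobec1 (1.65), the zinc finger gene Sall2 (1.61), the glycine receptor Glra1 (1.44), Rasgrp4 (1.43), the carbonic anhydrase Car14 (1.42), Tmem211 (1.39) and the erythropoietin receptor Epor (1.36). Of 13654 promoters 447 fell and 155 rose, 602 in all. With values as deposited, in which the median promoter stood at 0.11, 571 were lower and 373 higher. The count was 171 without WT line Mc3, 329 without WT line 57 and 342 without WT line 58, 1140 with 500 bases either side, and 1062 with edgeR.

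Promoters bivalent in hairpin cells without doxycycline were enriched among the 447, to an extent that depended on how the class was drawn. With both marks at least 1 log2 above input the share was 83.7% (374 promoters) against 3456 of all 13654 tested (25.3%), an odds ratio of 16.8 (95% interval 13 to 22, Fisher's exact test, two-sided, p = 5.32e-154). At 2 log2 above input it was 20.8% (93 promoters) against 1282 of all tested (9.39%), an odds ratio of 2.66 (2.07 to 3.37, Fisher's exact p = 9.51e-14). Among the 155 promoters that rose, 54 were bivalent (odds ratio 1.59, Fisher's exact p = 0.00897), a call that was lost with the class at 2 log2 above input (odds ratio 1.52).

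Polycomb marking and accessibility were asked at the same promoters. H3K27me3 also fell most at Twist2 (-5.03 ± 0.149 SE, n = 2 DKO and 3 WT lines, limma adjusted p = 1.04e-07). The adaptor Shc3 (-4.88), the galanin receptor Galr1 (-4.13), the dopamine receptor Drd5 (-4.09), the GABA transporter Slc6a11 (-4.09), the heat shock factor Hsf5 (-4.07) and the adhesion protein Svep1 (-4.04) were among the next largest falls. It rose at Efs (2.54), Gpc4 (2.26), Mthfd2l (2.00), Phlda3 (1.89), Fhl1 (1.80), Tnfrsf19 (1.77), the vasoconstrictor gene Edn1 (1.74) and Mppe1 (1.72). Of 4155 promoters 838 fell and 467 rose, 1305 in all. With values as deposited, whose median was 0.27, the split turned to 705 lower and 1290 higher. The count was 803 without WT line Mc3. Of the 838 falls 667 were bivalent, a smaller share than among the other tested promoters (odds ratio 0.559, Fisher's exact p = 1.79e-08).

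Accessibility fell at the neuronal adaptor Dab1 (-2.48 ± 0.322 SE, n = 3 lines each, limma adjusted p = 9.24e-05), at Myocd, a smooth muscle and cardiac coactivator (-2.36), and at Dpysl3 (-2.35), Arpp21 (-2.25), Htr4 (-2.21), Col19a1 (-2.18), Gucy1b3 (-2.15) and the tight junction gene Cldn5 (-2.15). Of 12983 promoters 183 fell and 0 rose by limma, where 911 had an unadjusted p under 0.05 and edgeR called 254 lower and 1 higher. With values as deposited, whose median was 0.20, 0 promoters were called by limma, and 83 had an unadjusted p under 0.05. The count was 69 without WT line 58 and 49 without WT line Mc3. Bivalent promoters made up 129 of the 183 (odds ratio 8.86, Fisher's exact p = 2.89e-45), but with the class at 2 log2 above input the odds ratio turned to 0.655.

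The 447 promoters with lower H3K4me3 were followed in libraries that had not chosen them. H3K27me3 had a median change of -1.28 at the 378 tested, with 266 lower and 39 higher (camera adjusted p = 2.8e-31, and 0.0259 with an estimated correlation). Accessibility had a median of -0.674, with 94 of 252 lower (camera adjusted p = 8.1e-72, and 0.00788 with an estimated correlation). With values as deposited the set drawn from them had 571 promoters, of which 496 and 291 were tested, with medians of -1.08 (323 lower, 43 higher) and -0.629 (0 called) and adjusted p = 0.115 and 0.0983 with an estimated correlation. The falls shared with H3K27me3 (266) and with accessibility (94) compare with 62.1 and 2.6 for independent lists. In single libraries of DKO clone 43 and WT clone 58, which have no replicate check, the median difference was -0.464 for EZH2 and -1.13 for RING1B, both Polycomb enzymes, -1.38 for the histone variant H2A.Z and -0.683 for Ash2l of the H3K4 methyltransferase complex. Each lay at percentile 0 of the matched random lists, whose medians were 0.0268, 0.00534, 0.00727 and 0.0507. With values as deposited the 571 promoters had medians of -0.212, -0.69, -0.815 and -0.6, again each at percentile 0. The matched lists then had medians of 0.339, 0.522, 0.495 and 0.11. Median CpG methylation was 8.98 percentage points higher in DKO clone 43 than in the mean of WT clones 57 and 58 over 442 promoters with a value (percentile 100; matched lists -3.19). The medians of the set were 60.67 and 49.38% in WT clones 57 and 58 and 68.92% in clone 43, in windows of 9380.5 bases at the median, far wider than a promoter. At Twist2 the single libraries differed by -2.55 (EZH2), -4.99 (RING1B), -4.77 (H2A.Z) and -2.24 (Ash2l), and methylation was 58.5% in WT and 89.9% in DKO cells. At Repin1 the differences were -0.459, -1.18, -3.24 and -1.11, with 71.6% and 72.4% methylation, and at Sstr4 they were -1.46, -3.21, -4.44 and -1.55, with 54.9% and 82.5%. Across Aatk, D1Pas1, Uggt2, Zfp629 and Htr4, the differences ran from -0.862 to 0.149 for EZH2 (above 0 at Zfp629), -2.79 to -0.512 for RING1B, -3.74 to -1.57 for H2A.Z and -1.17 to -0.288 for Ash2l, and methylation was 0.955 (Htr4) to 31.3 (D1Pas1) percentage points higher in DKO cells. RNA of the set in ESCs had a median of -0.322, with 21 of 195 genes lower, beside 0.127 for other genes (camera adjusted p = 2.8e-31, and adjusted p = 0.0808 with an estimated correlation).

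**Figure D2:**
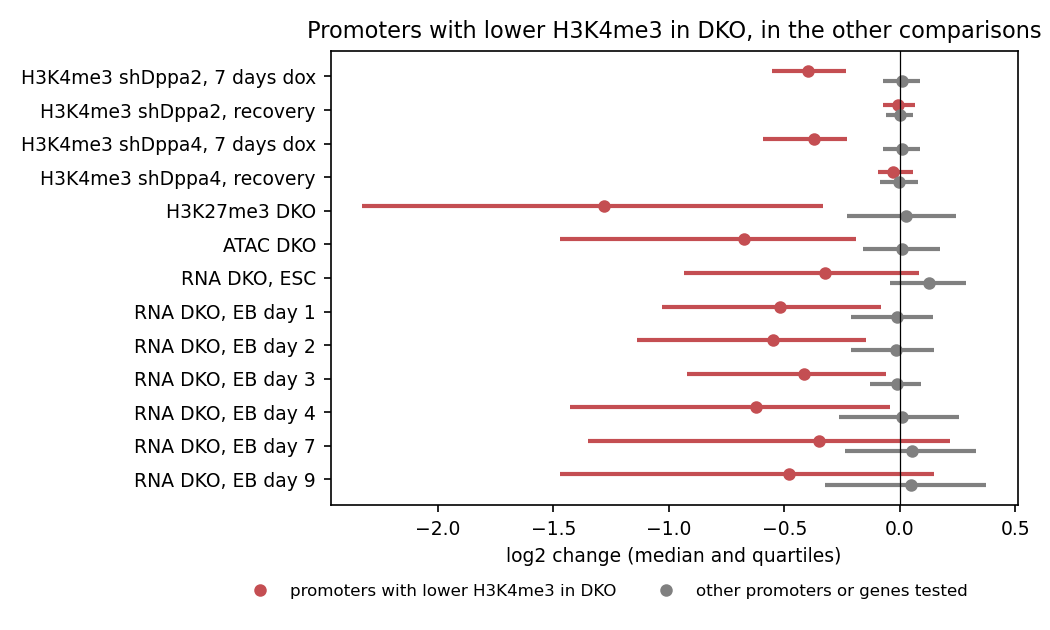
Median (point) and quartiles (line) of the log2 change for the 447 promoters with lower H3K4me3 in DKO cells and for the other promoters or genes tested, by library type. For the set, H3K27me3 in DKO cells had a median of -1.28 and accessibility -0.674. Hairpin changes are on the log2(RPM + 1) scale, which shrinks them at low signal, so their sizes do not compare with chromatin changes in DKO cells.

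The hairpin lines asked whether both marks changed when a hairpin against Dppa2 or Dppa4 was induced and whether they returned. RNA or protein of either gene in these lines is not among the values used here, so depletion and its reversal were not checked. No group was given doxycycline without such a hairpin, so effects of the hairpin and of doxycycline cannot be told apart. With 7 days of doxycycline, H3K4me3 fell most at Gnmt, a liver methyltransferase, in both lines, by -1.69 ± 0.126 (SE, n = 3 libraries each; limma adjusted p = 5.26e-10) with the Dppa2 hairpin and -1.77 ± 0.126 (limma adjusted p = 1.55e-10) with the Dppa4 hairpin. AC113533.1 (-1.54 and -1.70), Mosc1 (-1.10) and the heart and trophoblast factor Hand1 (-1.10) with the Dppa2 hairpin, and Sh2d4a (-1.29) and Cdcp1 (-1.21) with the Dppa4 hairpin, also fell. The largest rises were at Apobec1 (0.64), Ctbs (0.52), Renbp (0.51) and the zinc transporter Slc39a3 (0.51) in the former, and at Gpx8 (0.66), the cystine transporter Slc7a11 (0.61), Rufy3 (0.58) and BC033916 (0.52) in the latter. With the Dppa2 hairpin 541 promoters fell and 114 rose, 655 in all, and with the Dppa4 hairpin 542 fell and 152 rose, 694 in all. In fits with the replicate number as a block common to both lines, the counts were 1162 (851 lower) and 1226 (855 lower). For the Dppa2 hairpin 543 were lower and 912 higher with values as deposited (median 0.14), and the count was 197 and 128 without replicate 1 or 3. For the Dppa4 hairpin the count was 171, 1299 and 152 without replicate 1, 2 or 3.

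H3K27me3 fell with the Dppa2 hairpin at AC113533.1 (-1.54), Mosc1 (-1.19), Acot12 (-1.17) and the forkhead gene Foxi2 (-1.17 ± 0.102, limma adjusted p = 3.57e-09), and with the Dppa4 hairpin at AC113533.1 (-1.40), the limb and lung gene Tbx4 (-1.14 ± 0.12, limma adjusted p = 2.11e-07) and Mosc1 (-1.04). It rose at Mppe1 (0.99), Klhdc5 (0.75), AW555464 (0.72) and the Notch ligand Jag2 (0.69), and at Myo5a (0.98), Zfp777 (0.89), Shc2 (0.84) and Rnf157 (0.80). In all 322 promoters fell and 157 rose with the Dppa2 hairpin (479), and 299 fell and 257 rose with the Dppa4 hairpin (556). Fits with that block gave 721 (434 lower) and 850 (437 lower). Without replicate 1 or 3 the counts were 146 and 136 for the Dppa2 hairpin and 153 and 93 for the Dppa4 hairpin, and with values as deposited 69 and 72 (medians 0.09 and 0.13).

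The promoters that lost H3K4me3 in DKO cells moved with the hairpins. Their median H3K4me3 change with doxycycline was -0.398 with the Dppa2 hairpin, where 255 of the 447 fell (camera adjusted p = 3.03e-94), and -0.373 with the Dppa4 hairpin, where 243 fell (3.23e-86). Both tests held at adjusted p = 6.42e-05 with an estimated correlation, and 17.7 shared falls would be found between independent lists in either case. Sizes of change in the hairpin lines do not compare with those in DKO cells, since the pseudocount of the hairpin values shrinks changes at low signal. H3K27me3 had medians of -0.131 (95 lower, 15 higher; camera adjusted p = 1.87e-09, and 0.0246 with an estimated correlation) and -0.12 (82 lower, 32 higher; camera adjusted p = 2.26e-06, but adjusted p = 0.0524 with an estimated correlation). With values as deposited, where the set drawn from them had 571 promoters, the H3K27me3 medians were -0.0359 (11 lower, 3 higher) and 0.00623 (9 lower, 3 higher) beside 0.106 and 0.142 at other promoters, and both had adjusted p = 0.679 with an estimated correlation.

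After recovery most of this was not called. The Dppa2 hairpin line had 0 promoters changed against cells never given doxycycline for H3K4me3 (by limma, with 625 at an unadjusted p under 0.05, and 0 by edgeR). For H3K27me3 it had 0 (130 at an unadjusted p under 0.05, 0 by edgeR, and 2 in the fit with the block). The Dppa4 hairpin line had 0 for H3K27me3 (338 at an unadjusted p under 0.05, 0 by edgeR, 192 without replicate 2) but 145 for H3K4me3, 69 lower and 76 higher. These included falls at Lrrc31 (-0.80), Ndufa4l2 (-0.74), the neurofilament gene Nefm (-0.68) and Zfp575 (-0.54) and rises at BC033916 (0.60), Rufy3 (0.53), the histone gene Hist1h3g (0.49) and Ccdc101 (0.46). That count was 1399 without replicate 2, 0 without replicate 1 and 0 without replicate 3, and with values as deposited 34 were lower and 2 higher. With the replicate number as a block, the Dppa4 hairpin line had 556 for H3K4me3 and 21 for H3K27me3 in recovery. Its numbers had been taken as unpaired there. At the 447 promoters the median H3K4me3 change after recovery was -0.00749 and -0.0309, with 0 lower in either line (camera adjusted p = 0.544 and 0.166). H3K27me3 medians were -0.0222 (camera adjusted p = 0.0484, and adjusted p = 0.385 with an estimated correlation) and -0.0433 (0.00544, and adjusted p = 0.229 with an estimated correlation). From doxycycline to recovery the set rose in H3K4me3 by medians of 0.38 and 0.34, with 239 and 210 promoters called higher (camera p = 2.71e-06 and 5.18e-06 with an estimated correlation), in a contrast chosen after seeing the data. In H3K27me3 the medians were 0.118 (72 higher, p = 0.0216 with an estimated correlation) for the Dppa2 hairpin and 0.0816 (47 higher, p = 0.114 with an estimated correlation) for the Dppa4 hairpin. The difference between both hairpins was tested itself and called 1 promoter for H3K4me3 with doxycycline and 0 in the other contrasts (limma; 996, 232 and 151 at an unadjusted p under 0.05).

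Overexpression asked the opposite question. Dppa2 stood at 127 to 132 and 188 to 195 RPM in Dppa2-GFP clones c3 and c5 and at 77.6 to 89.1 RPM in GFP clones, and Dppa4 at 168 to 187 and 101 to 110 RPM in Dppa4-GFP clones c5 and c6 and at 76.9 to 97.7 RPM in GFP clones. Neither difference passed the test (Dppa2 0.90 ± 0.208, limma adjusted p = 0.586; Dppa4 0.62 ± 0.21, limma adjusted p = 0.92; SE, n = 2 clones each). All 26 measured 2-cell-like genes passed in Dppa2-GFP clones when adjusted over the list alone and 0 when adjusted over all genes, with a median of 1.5 (camera adjusted p = 1.6e-37, and adjusted p = 0.534 with an estimated correlation). In Dppa4-GFP clones 23 of 26 passed adjusted over the list alone, with a median of 1.11 (camera adjusted p = 1.31e-21, and adjusted p = 0.505 with an estimated correlation). Zscan4c, of a telomere-linked family, stood at 8.66 ± 1.19 RPM in Dppa2-GFP, 7.16 ± 3.03 in Dppa4-GFP and 2.05 ± 0.572 in GFP clones (SD, n = 2 each), and Zscan4f at 6.36 ± 1.08, 4.43 ± 1.12 and 1.35 ± 0.569 RPM, neither past the test over all genes.

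Grb10, an imprinted growth inhibitor, was the 1 gene that changed in Dppa2-GFP clones, falling from 314 ± 35.3 to 81.4 ± 0.584 RPM (-1.93 ± 0.0862, limma adjusted p = 0.00106). In ESCs Grb10 ran from 13.6 to 154 RPM between WT lines. With 2 clones each, an effect of Dppa2-GFP on Grb10 cannot be told apart from differences between these clones. Other imprinted genes were higher without passing over all genes, namely Plagl1 (35.1 ± 1.39 and 1.24 ± 0.993 RPM), Peg10 (782 ± 100 and 286 ± 152 RPM) and Mest (1.14), and 9 of 31 imprinted genes passed adjusted over the list alone (median 0.536, camera adjusted p = 1.9e-05). The trophoblast list (median 0.62, 1 alone adjusted over the list alone, adjusted p = 2.79e-05) and the mesoderm list (median 0.471, adjusted p = 0.0463) were also called higher. These 3 had an adjusted p = 0.534, 0.619 and 0.62 with an estimated correlation. In Dppa4-GFP clones 0 genes passed (limma; 745 at an unadjusted p under 0.05, 0 by edgeR), and 5 lists were called lower by camera with medians near 0, COMPASS (-0.0643, adjusted p = 4.35e-05), DNA methylation machinery (-0.0515, 0.00376), germline (-0.101, 0.000462), naive pluripotency (-0.0262, 0.031) and mitochondrially encoded (0.0177, with a median of -0.0601 but a mean of 0.0809). None of these 5 was called with an estimated correlation, at an adjusted p = 0.505 for COMPASS and DNA methylation machinery, 0.634 for germline and mitochondrially encoded and 0.72 for naive pluripotency with an estimated correlation. In Dppa2-GFP clones the count was 964 without GFP clone c2, 2 without GFP clone c1, 0 without Dppa2-GFP clone c3 and 2 without c5, and in Dppa4-GFP clones 417 without GFP clone c2 and 2 without GFP clone c1 or Dppa4-GFP clone c5, where a lone clone is taken to vary like the others.

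In embryoid bodies the question was how DKO cells differentiated, with 1 clone per genotype. On days 1 and 2 germline genes were again lower in DKO libraries. Ddx4 was listed at 0 RPM in DKO libraries on day 1 and at 15.9 to 20.5 RPM in WT libraries, and fell by 4.16 on the log2 scale on day 2 (limma adjusted p = 4.08e-05). Sohlh2 (listed at 0 RPM against 6.7 to 8.56 RPM), the acetyltransferase Naa11 (-2.95) and Syce1 (-3.14) fell on day 1 and Tdrd1 of the piRNA pathway (-2.34) on day 2. Of 32 germline genes 11 fell on either day, with 1 and 2 higher, and 17 and 15 passed adjusted over the list alone (medians -0.633 and -0.493, camera adjusted p = 1.15e-08 and 6.34e-07, and adjusted p = 0.334 and 0.614 with an estimated correlation). Cdkn1c, an imprinted cell cycle inhibitor, rose from 41.2 ± 5.38 to 281 ± 72.3 RPM on day 1 (SD, n = 3; 2.71 ± 0.435, limma adjusted p = 0.000204) and by 2.90 on day 2. Dmbx1 (2.01), Fry (2.69) and the endoderm regulator Hnf4a (1.97) rose on day 1, and Car4 (-3.85), Rpl10l (-3.74), Prpf39 (-3.64) and Krt19 (-2.90) fell. Klhl13 (-3.69) and Repin1 (-3.60) fell on day 2.

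Day 1 had 627 genes changed, 125 higher and 502 lower, and day 2 had 433, 78 higher and 355 lower. Quantile normalization gave 177 higher and 314 lower, and 121 higher and 258 lower. With each day fitted alone the counts were 389 higher and 848 lower on day 1 and 15 higher and 111 lower on day 2. Endoderm (4 of 27 lower, 1 higher, adjusted p = 0.0142), trophoblast (2 of 17, 0.00333), fibroblast (2 of 20, 0.0472) and p53 response lists (1 of 20, 5 adjusted over the list alone, 0.0142) were called lower by camera on day 1, with adjusted p = 0.884 with an estimated correlation for endoderm, trophoblast and p53 response and 0.9 for fibroblast. On day 2 mesoderm (0 of 24, adjusted p = 0.00224), endoderm (0.0148) and trophoblast lists (0.0476) were lower, all at adjusted p = 0.914 with an estimated correlation. The trophoblast call was lost in the fit with the set as a block common to all days (camera adjusted p = 0.064). Without set 1, 2 or 3 the counts were 205, 157 and 211 on day 1 and 220, 142 and 36 on day 2.

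Directions on day 3 draw on the library labelled WT of set 2, which went against its label for Dppa4. Parva, an adhesion protein, fell from 12.8 ± 5.72 to 0.621 ± 0.193 RPM (-3.00 ± 0.238, limma adjusted p = 3.68e-09, n = 3). Gpx3 (-2.39), the desmosome gene Dsc2 (-2.22), Gatm (-2.21) and Tdrd1 (-1.70) also fell, and Cdkn1c (2.34), Mtus2 (1.40) and Piwil1 (0.96) rose. Of 24 mesoderm and primitive streak genes 0 were called but 12 passed adjusted over the list alone (median -1.01, camera adjusted p = 2.84e-13, and adjusted p = 0.172 with an estimated correlation). Brachyury (T) stood at 445 and 184 RPM in WT sets 1 and 3, at 5.36 RPM in the library labelled WT of set 2, and at 1.34 to 18.6 RPM in DKO libraries. Without that library 9 of the 24 were lower (median -1.45, camera adjusted p = 2.82e-17, and 0.0376 with an estimated correlation). The lists of germline (2 lower, 1 higher, adjusted p = 0.00177), endoderm (0.00847) and trophoblast (0.0234) were lower and those of neuroectoderm (0.0161) and primed pluripotency (0.0457) higher, each at adjusted p = 0.842 with an estimated correlation. The imprinted list was called higher (adjusted p = 0.014, mean 0.206) with a median of -0.0255 and an adjusted p = 0.725 with an estimated correlation, and lost its call without that library (0.229), as did neuroectoderm (0.0529). In all 60 genes changed, 11 higher and 49 lower, and 290 without the library labelled WT of set 2 (43 higher, 247 lower), which held each of the 60. With day 3 fitted alone 0 genes were called by limma, with or without the set as a block in a paired fit (1415 and 1127 at an unadjusted p under 0.05). The count was 3, 183 and 1 without set 1, 2 or 3.

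On day 4 mesoderm genes were far lower in DKO libraries. Kdr, the VEGF receptor of blood and vessel progenitors, fell from 252 ± 131 to 5.07 ± 0.184 RPM (-5.20 ± 0.387, limma adjusted p = 1.05e-10, n = 3), Mesp1, an early cardiac mesoderm factor, from 62.1 ± 15.1 to 0.267 ± 0.193 RPM (-5.62), and Hand1 from 169 ± 109 to 0.184 ± 0.319 RPM (-6.86). Wnt5a (-6.22), Nrp1 (-6.15), Prdm6 (-5.74), Pdgfra (-4.77), Gata3 (-4.47), Hoxd9 (-4.52), Fn1 (-4.17), Tbx3 (-4.13), Msgn1 (-3.95), Gata4 (-2.98), Isl1 (-2.62), Sox17 (-2.56) and Hoxb8 (-2.50) fell with them. The imprinted growth factor Igf2 fell from 616 ± 486 to 13.7 ± 0.489 RPM (-4.82). Grb10 rose from 10 ± 2.73 to 454 ± 120 RPM (5.37), and Pou3f1, of the primed epiblast and neural cells, from 17.7 ± 4.82 to 304 ± 184 RPM (3.90). Slc27a2 (4.01), Calcr (3.76), Fgf4 (2.40), the eye and neural gene Pax6 (2.06) and the DNA methyltransferase Dnmt3b (1.93) rose too.

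By list, 17 of 24 mesoderm genes fell on day 4 (18 adjusted over the list alone, median -2.36, camera adjusted p = 7.44e-17, and adjusted p = 0.0712 with an estimated correlation). Of 36 Hox genes 24 fell (26 adjusted over the list alone, median -1.39), of 20 cardiac genes 9 (11 alone, -0.968), of 27 endoderm genes 12 (13 alone, -0.596), of 17 trophoblast genes 11 (-1.35) and of 20 fibroblast genes 10 (13 alone, -1.3), with camera adjusted p = 1.98e-11, 2.79e-06, 3.8e-05, 1.19e-05 and 7.1e-05 and each at adjusted p = 0.254 with an estimated correlation. Of 26 blood and endothelial genes 8 fell (9 alone, adjusted p = 0.00171, and adjusted p = 0.729 with an estimated correlation). Among primed pluripotency genes 5 of 15 rose and 1 fell (8 alone, median 1.27, adjusted p = 0.000208, and adjusted p = 0.445 with an estimated correlation). Day 4 had 2579 genes changed, 1078 higher and 1501 lower. The count was 1166 without set 2 and 835 without set 3.

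**Figure D3:**
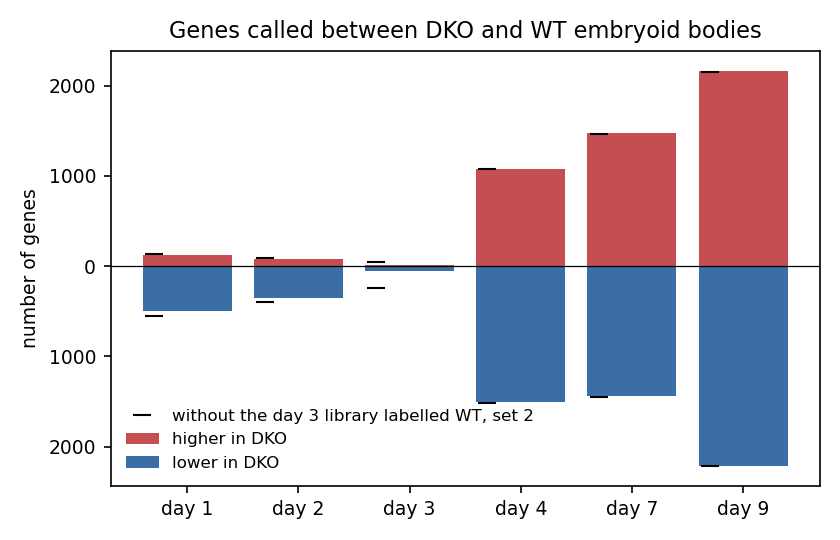
Genes higher (upward) and lower (downward) in DKO than in WT embryoid bodies at a limma adjusted p under 0.05, by day. Bars run from 60 genes on day 3 to 4378 on day 9, and black ticks give the counts without the library labelled WT of set 2 at day 3. The bars rest on 1 spread shared by all days. With each day fitted alone, day 1 had 1237 genes and day 9 had 1014, or 559 and 2036 with the set as a block.

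On days 7 and 9 mesenchymal and matrix genes were lower and neural genes higher in DKO libraries. Postn, a matrix protein, fell from 611 ± 72.2 to 2.14 ± 2.54 RPM on day 7 (-7.91 ± 0.797, limma adjusted p = 1.93e-08, n = 3) and from 2590 ± 855 to 104 ± 168 RPM on day 9 (-6.68). Lum, a collagen-binding proteoglycan, fell from 193 ± 42.9 to 1.19 ± 1.1 RPM on day 9 (-6.56 ± 0.235, limma adjusted p = 1.82e-18), Col3a1 from 3940 ± 1810 to 205 ± 296 RPM (-5.54), and Dcn (-5.40), Mab21l2 (-6.70), Dsc2 (-5.76) and Pgm5 (-5.41) fell too. Twist2 was listed at 0 RPM in DKO libraries of both days and at 52.3 to 65.8 and 45.2 to 54.9 RPM in WT libraries. The embryonic globins Hbb-y (280 ± 79.8 to 2.28 ± 3.08 RPM, -6.79) and Hba-x (-6.42), the hindlimb gene Pitx1 (-6.03) and the serum transporter Ttr (-3.73) fell on day 7. The Hox gene Hoxa10 fell on both days (-3.49 and -3.53), as did Cd34 (-3.35 and -2.58). On day 9 the placental gene Plac1 (-3.33), Krt19 (-3.90) and the death receptor Fas (-4.05) fell.

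Grb10 rose most on both days, from 9.35 ± 2.01 to 1190 ± 267 RPM on day 7 (6.84) and from 11.9 ± 0.897 to 1380 ± 458 RPM on day 9 (6.69 ± 0.522, limma adjusted p = 6.28e-11). On day 7 the neural genes Sox1 (4.01) and Pax6 (3.01), the streak genes Eomes (3.35), Hoxb1 (3.24) and Mesp1 (3.07), and Zic2 (3.26) rose, and Bmper (3.53). On day 9 the neural genes Zic1 (2 ± 0.945 to 33.8 ± 20.2 RPM, 3.33) and Pax3 (0.444 ± 0.254 to 16.9 ± 13.1 RPM, 3.17), the organiser gene Lhx1 (3.41), Fgf8 (3.21), Ppp1r1a (3.18), Calcr (3.12), the cartilage and notochord collagen Col2a1 (2.97), the pluripotency-linked Lin28a (2.45), Lin28b (2.05) and Sox2 (1.84) rose, the last with groups that overlapped (30.7 to 306 RPM in DKO and 19.7 to 49.1 RPM in WT libraries). Of 27 neuroectoderm genes 13 rose on day 7 and 21 on day 9 (16 and 23 adjusted over the list alone, medians 1.08 and 1.48, camera adjusted p = 8.6e-07 and 1.88e-09), with adjusted p = 0.514 and 0.358 with an estimated correlation. Of 20 fibroblast and mesenchyme genes 16 fell and 1 rose on either day (17 and 19 adjusted over the list alone, medians -2.26 and -3.3, camera adjusted p = 2.3e-16 and 4.72e-17). This list was also called with an estimated correlation (adjusted p = 0.0158 and 0.0129 with an estimated correlation).

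Other lists were called on days 7 and 9. Primed pluripotency genes rose in 7 and 11 of 15 (9 and 12 adjusted over the list alone, camera adjusted p = 7e-05 and 3.17e-05, and adjusted p = 0.514 and 0.49 with an estimated correlation). Hox genes fell in 18 and 20 of 36, with 2 higher on either day (22 and 23 alone, 1.04e-06 and 2.47e-06, and adjusted p = 0.514 and 0.49 with an estimated correlation). Trophoblast genes fell in 5 and 7 of 17 (0.0082 and 0.00021, and adjusted p = 0.52 and 0.49 with an estimated correlation). On day 7 mesoderm genes, among them Mesp1 and Hoxb1, were higher in 10 of 24 and lower in 2 (15 alone, median 1.22, adjusted p = 0.00203), and 4 of 13 COMPASS genes were higher (0.0304), both at adjusted p = 0.52 with an estimated correlation. Blood genes fell in 10 of 26 with 1 higher (15 alone, adjusted p = 6e-06), endoderm genes in 11 of 27 with 5 higher (18 alone, 0.00297) and imprinted genes in 8 of 30 with 4 higher (14 alone, 0.0336), each at adjusted p = 0.514 with an estimated correlation. On day 9 naive pluripotency genes rose in 5 of 22 (4 alone, median 0.96, adjusted p = 0.00222, and adjusted p = 0.81 with an estimated correlation). Imprinted genes fell in 10 of 30 with 5 higher (19 alone, adjusted p = 0.0489, and adjusted p = 0.49 with an estimated correlation). This call was lost in the fit with the set as a block common to all days (camera adjusted p = 0.0509). The Polycomb, heat shock and unfolded protein, and housekeeping lists were called in 0 of the 10 RNA comparisons, with lowest camera adjusted p of 0.0965, 0.305 and 0.248.

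**Figure D4:**
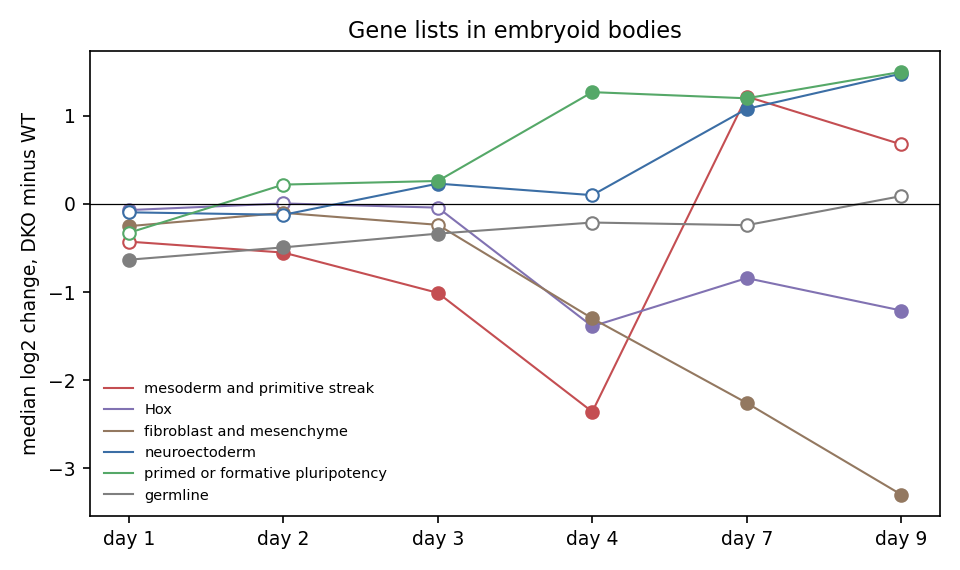
Median log2 change of gene lists (DKO minus WT, vertical axis) by day of embryoid body culture (horizontal axis), filled where the camera adjusted p was under 0.05. The fibroblast and mesenchyme list reached -3.3 and the neuroectoderm list 1.48 on day 9.

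Day 7 had 2910 genes changed, 1470 higher and 1440 lower, and day 9 had 4378, 2167 higher and 2211 lower. Fitted alone without the set as a block, day 7 had 451 higher and 822 lower and day 9 had 336 higher and 678 lower. With the block, day 9 fitted alone had 2036 genes and day 1 had 559. Without the block day 9 had 1014 and day 1 had 1237. Whether day 9 had more calls than day 1 thus depended on the fit. Dppa2 fell on day 9 (-0.85, limma adjusted p = 0.0344) although its groups overlapped, and was -0.81 on day 7 (0.0593), while Dppa4 was 0.33 and 0.67 (0.603 and 0.208). Day 7 had 1398 and 1264 without set 2 or 3, and day 9 had 2142 and 2520. The change in the DKO effect from day 1 to day 9 was tested itself, and 2503 genes differed, 1341 upward and 1162 downward, with 753 and 1003 without set 2 or 3. By list it was downward for fibroblast genes (13 of 20, 16 adjusted over the list alone, median -2.69, camera adjusted p = 7.22e-13, and 0.0474 with an estimated correlation) and Hox genes (16 of 36, 2 upward, 22 alone, 5.73e-06), and upward for neuroectoderm (17 of 27, 18 alone, median 1.59, 1.5e-08), germline (13 of 32, 16 alone, 0.000125) and primed pluripotency genes (6 of 15, 11 alone, 0.000262). The last 4 had adjusted p = 0.6, 0.455, 0.6 and 0.628 with an estimated correlation.

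Genes of the promoters that lost H3K4me3 in DKO ESCs were lower in RNA throughout differentiation. Over days 1, 2, 3, 4, 7 and 9 the medians of 252 such genes were -0.518, -0.548, -0.415, -0.623, -0.348 and -0.48, with 55, 62, 25, 105, 91 and 99 lower and 0, 0, 0, 6, 22 and 23 higher. Each camera test held with an estimated correlation (adjusted p = 0.00788, 0.00348, 0.00122, 0.0192, 0.0396 and 0.0476). Lists called independently would share 8.01, 5.45, 0.697, 26, 22.7 and 38.3 falls. Without the library labelled WT of set 2 at day 3, the day 3 median was -0.605 with 71 genes lower. Twist2, with the largest H3K4me3 fall, was among them on days 7 and 9.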

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

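The bounds of every test of an explanation in this part, the contrasts between both hairpins and both overexpressed genes, and the fits without the library labelled WT of set 2 at day 3 were chosen after the results were seen, while the change of the DKO effect from day 1 to day 9 was planned.

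Between day 1 and day 9 the DKO effect itself differed for 2503 genes (limma). Between overexpressed genes 1 gene differed, Grb10, at -2.23 ± 0.0862 (SE) for Dppa2-GFP minus Dppa4-GFP clones (limma adjusted p = 0.000386, n = 2 clones each). Grb10 also varied between WT lines of ESCs (13.6 to 154 RPM), so differences between clones cannot be told apart from an effect of the overexpressed gene. Between hairpins 1 promoter differed in its H3K4me3 response to doxycycline, that of 7530422B04Rik, at 0.745 ± 0.0946 for the Dppa4 minus the Dppa2 hairpin (limma adjusted p = 0.000127, n = 3 libraries each), a promoter outside the rule for named genes and chosen after its values were seen.

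Single libraries stood far from their group in 4 of 29 sets of values tested, where chance marks about 1 in 20. WT library C of line 58 took 22.35% of its gene reads from mitochondria (others 0.564% to 6.167%). DKO library B of line 36 had 75.65% of reads on genes (others 85.32% to 88.52%). WT libraries B and C of line 58 were lower still (73.85% and 75.06%), beside 83.79% to 90.28% in the other WT libraries. The rule, which looks for 1 value apart, did not mark these. DKO library A of line 43 had 50.3 RPM of Dppa4 (others 13.7 to 26.8 RPM). ATAC-seq library B of DKO line 53 had 44.96 M mapped reads (others 17.69 to 26.75 M). Library B of clone 43 in the second ESC table, used only in an added alternative, held 823345 reads on genes, with Dppa2 at 0 RPM, Dppa4 at 1.52 RPM, Nanog at 197 RPM and Pou5f1 at 17.5 RPM.

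By correlation between libraries, the library labelled WT of set 2 at day 3 was closer to the DKO than to the other WT libraries of that day. Its lowest correlation with a DKO library was 0.988 and its highest with another WT library 0.983. It also resembled DKO libraries in several genes, chosen after their values were seen. Ddx4 stood at 0.112 RPM (other WT 14.4 and 20.2 RPM), Repin1 at 0 RPM (24.8 and 24.7 RPM), Grb10 at 302 RPM (at most 26 RPM in the other WT libraries, 189 to 304 RPM in DKO libraries) and T at 5.36 RPM, but Dppa2 at 28.8 RPM was above the DKO libraries (4.26 to 6.19 RPM), which argues against a DKO clone 43 library under a WT label. A swap within day 3 would need a DKO library with WT levels of Ddx4, and the highest held 0.445 RPM. A mixture of both genotypes is argued against by Ddx4 at 0.647% and Dppa2 at 117% of the mean of the other WT libraries. A label from another day of these embryoid bodies is argued against. No DKO library of any day exceeded 13.2 RPM of Dppa2, and the WT set 2 libraries of other days had 2.21 to 17.6 RPM of Ddx4. A sample from outside these embryoid bodies, another DKO clone and a different line lacking Dppa4 alone stay open. In ESCs DKO line 53 held 20.5 to 25.4 RPM of Dppa2 and 18.9 to 26.8 RPM of Dppa4. These levels do not compare directly with day 3, since DKO clone 43 went from 9.42 to 16.9 RPM of Dppa2 in ESCs to 4.26 to 6.19 RPM. No biological explanation was tested.

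Grb10, Cdkn1c and Phlda2 (the last outside the rule for named genes), 3 imprinted growth regulators, were higher in DKO than in WT embryoid bodies, where WT clone 58 and DKO clone 43 stand for the genotypes. In ESCs WT clone 58 had 13.6, 36.7 and 29.2 RPM of these, while the highest other WT line had 154, 101 and 78.3 RPM. DKO lines had 107 to 155, 152 to 206 and 72 to 136 RPM. For Phlda2 both other WT lines (77.9 and 78.3 RPM) reached the DKO range, so a low level in clone 58 alone may account for the difference. For Grb10 WT line 57 reached it but Mc3 held 75.7 RPM, so a low level in clone 58 alone remains open. For Cdkn1c both other WT lines stayed below the DKO range, and this remains open too. Loss of Dppa2 and Dppa4 also stays open, since the lowest limma adjusted p of the 3 genes in ESCs was 0.0646 (Cdkn1c), and a p that misses the threshold does not show equal levels.

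The higher 2-cell-like genes in overexpression clones rest on 2 GFP clones that differ, with 25 of 26 genes higher in GFP clone c2 than in c1 (median difference 0.399). A low level in GFP clone c1 alone is argued against for the Dppa2-GFP clones, whose lowest median difference from GFP clone c2 was 1.21, with 26 of 26 genes higher. Both Dppa4-GFP clones had 24 of 26 genes higher than GFP clone c2, by medians of 1.27 (clone c5) and 0.474 (clone c6). The latter is close to the difference between the GFP clones, so for clone c6 a low GFP clone c1 could explain part of the rise over the GFP mean, and this stays open. Overexpression of Dppa2 or Dppa4 is the explanation the design names, and with 2 clones each it was not separated from differences between clones.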

How the results depend on the processing

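The edgeR fits, each embryoid body day fitted alone, the fits without doubted libraries or with library B of clone 43, the block in list tests and the estimated correlation for the promoter set were chosen after the data were seen. Of 2621 values of named genes under alternatives 2284 kept direction and side of the threshold, 275 lost a call, 62 gained one and 0 reversed. Of 1853 values of gene lists 1681 were kept, 121 lost, 45 gained and 6 reversed. Of 309 counts and other values 213 were kept. The cause of each change was not tested unless given here. Fits without a replicate have fewer samples. The polyA alternatives and the threshold of 0.01 for the overlap of total and polyA RNA were not run, since both tables held the same values. In simulated data the test recovered 16% of log2 changes of 1 in ESC RNA, and the part that depth plays in this was not tested.

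Without 1 replicate the counts ran from 31 to 177 for ESC RNA, 0 to 964 for Dppa2-GFP, 0 to 417 for Dppa4-GFP, 157 to 211 on day 1, 36 to 220 on day 2, 1 to 183 on day 3, 835 to 2484 on day 4, 1264 to 2087 on day 7, 2142 to 3689 on day 9, 753 to 1869 for the change between days, 171 to 628 for H3K4me3, 803 to 1853 for H3K27me3 (803 to 926 without a WT line; without a DKO line the lone other one is taken to vary like the WT lines) and 49 to 254 for accessibility in DKO cells. With the Dppa2 hairpin they ran from 128 to 818 (H3K4me3) and 136 to 618 (H3K27me3), and in recovery from 0 to 2 and 0 to 3. With the Dppa4 hairpin they ran from 152 to 1299 and 93 to 742, and in recovery from 0 to 1399 and 0 to 192.

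Values as deposited called 944 promoters for H3K4me3, 1995 for H3K27me3 and 0 for accessibility in DKO cells, 1455 and 69 for both marks with the Dppa2 hairpin, 72 for H3K27me3 with the Dppa4 hairpin and 36 for H3K4me3 in its recovery. With 500 bases either side H3K4me3 had 1140 in DKO cells and 82 in recovery of the Dppa4 hairpin. No filter gave 118 for accessibility, 1103 for H3K4me3 with the Dppa4 hairpin and 5 in its recovery. edgeR gave 1062 for H3K4me3 in DKO cells and 1148 with the Dppa2 hairpin.

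Single libraries with clone as a random effect gave 245 genes in ESCs, 291 for Dppa2-GFP and 101 for Dppa4-GFP, and with the library letter or number as a replicate block as well 194, 174 and 64. Letters and numbers only share a name there (lowest correlation -0.542 and -0.0808). Library B of clone 43 added gave 160 genes. Each day alone gave 1237, 126, 0, 1273 and 1014 genes on days 1, 2, 3, 7 and 9, and with the set as a block 100, 0 and 2036 on days 2, 3 and 9. Without the library labelled WT of set 2, day 3 had 290.

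The replicate block gave 1162 (Dppa2 hairpin) and 1226 (Dppa4 hairpin) for H3K4me3 and 721 and 850 for H3K27me3 with doxycycline, and 2 for H3K27me3 in recovery of the Dppa2 hairpin. In recovery of the Dppa4 hairpin, where the numbers were taken as unpaired (lowest correlation 0.0255 and 0.0733), it gave 556 and 21. The block was the same over all 18 libraries of a mark, so it could not be paired in 1 contrast and unpaired in another. For H3K4me3 in that recovery, numbers 2 and 3 correlated best with their own number (0.125 and 0.0937), while number 1 did not. The set as a block gave 729 genes on day 1 and 66 on day 3, taken as unpaired (lowest correlation 0.0385 and -0.0815). On day 1 each DKO library still correlated best with the WT library of its own number. With the set as a block common to all days, days 2, 4, 7 and 9 had 495, 2868, 3384 and 4834 genes. Pairing within the day, with day 9 fitted alone, gave 2036 genes on day 9. On day 1 the fibroblast list went to an adjusted p of 0.0524 with the block. Beyond these and the calls given with their results, the block changed no other list or promoter set call, except that of the promoter set with values as deposited for H3K4me3 in recovery of the Dppa4 hairpin (adjusted p from 0.0364 to 0.11).

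With an estimated correlation 3 of the 61 list calls held. In embryoid bodies this correlation came from all libraries, the one labelled WT of set 2 at day 3 included. Without that library the promoter set's unadjusted camera p with an estimated correlation went from 0.00278 to 4.09e-05 on day 1. On day 9 it went from 0.0308 to 0.00239. Lists were tested that way without that library on day 3 alone. The mitochondrially encoded list in ESCs reversed with quantile normalization (camera adjusted p = 0.988), without libraries under 80% of reads on genes (0.262) and with library B of clone 43 (0.255). In Dppa4-GFP clones naive pluripotency reversed without clone c6 (0.993; 0.00014 without clone c5, the lowest without 1 clone), trophoblast without GFP clone c1 (5.71e-05; 0.886 without clone c5, the highest) and Hox without a filter (0.0115). The promoter set gained a call with values as deposited in recovery of H3K4me3 (2.87e-07 for the Dppa2 and 0.0364 for the Dppa4 hairpin), lost again with an estimated correlation (adjusted p = 0.29 and 0.679). It lost calls with an estimated correlation for H3K27me3 with the Dppa4 hairpin (0.0524), in recovery of either hairpin (0.385 and 0.229) and in ESC RNA (0.0808), and for H3K27me3 in recovery of the Dppa2 hairpin with values as deposited (0.113). With both marks 2 log2 above input the odds ratio of bivalent promoters was 2.66 for H3K4me3 falls, still called, and 1.52 for H3K4me3 rises, no longer called. For accessibility falls it was 0.655, under 1 but not called (Fisher's exact p = 0.191).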

Other observations

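The fits without the library labelled WT of set 2 at day 3 and the contrasts of recovery with doxycycline were chosen after the results were seen; the splits of samples were planned.

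Genes of the primitive streak, the structure from which mesoderm arises, are given here by day, without a test between days. T was 76.6 ± 95.4 RPM in WT and 1.31 ± 0.852 RPM in DKO libraries on day 2 (SD, n = 3; limma adjusted p = 0.0828). On day 3 Evx1 (-3.28, limma adjusted p = 0.106) and Mixl1 (-3.03, limma adjusted p = 0.312) did not pass, with WT sets 1 and 3 at 61.3 and 29.3 RPM of Evx1 and 93.9 and 39.1 RPM of Mixl1, but the library labelled WT of set 2 at 0.782 and 1.12 RPM, inside or below the DKO range (0 to 1.45 and 1.22 to 2.03 RPM). On day 4 Mesp1 (-5.62) and Msgn1 (-3.95) fell. On day 7 Mesp1 (3.07), Hoxb1 (3.24) and Eomes (3.35) were higher in DKO libraries. The median of the mesoderm list was -0.552, -1.01, -2.36 and 1.22 on days 2, 3, 4 and 7, and -1.45 on day 3 without the library labelled WT of set 2. These 4 list calls were lost with an estimated correlation (adjusted p = 0.914, 0.172, 0.0712 and 0.52 with an estimated correlation), but the day 3 call held without that library (0.0376). Dppa3, an oocyte and naive pluripotency gene, fell on days 1 (-1.99) and 2 (-1.86) and stood at -1.19 in ESCs (limma adjusted p = 0.241). Hells, a chromatin remodeller of DNA methylation, fell on day 1 (-0.94).

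Falls in both marks were shared between experiments that had no library in common. Of the promoters lower in H3K4me3 with doxycycline, 320 were shared by the Dppa2 and the Dppa4 hairpin, where independent lists would share 21.5. Both lines were given doxycycline, and an effect of doxycycline itself cannot be told apart in this overlap. For H3K27me3 the DKO falls shared 280 promoters with the Dppa2 hairpin and 241 with the Dppa4 hairpin, where independent lists would share 64.9 and 60.3. From doxycycline to recovery, 406 promoters rose and 86 fell in H3K4me3 with the Dppa2 hairpin and 356 rose and 80 fell with the Dppa4 hairpin, and in H3K27me3 250 rose and 144 fell and 198 rose and 143 fell (limma).

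Each comparison of 3 against 3 allows 10 splits of its samples, too few for a share under 0.05. The real split had the most calls, so that 1 of 10 splits reached it, for ESC RNA (93, highest other 0), embryoid bodies on days 1 (627, 0), 2 (433, 0), 3 (60, 0), 4 (2579, 12), 7 (2910, 0) and 9 (4378, 1543), the change between days 1 and 9 (2503, 2), H3K4me3 (602, 0) and accessibility (183, 26) in DKO cells, H3K4me3 with the Dppa2 (655, 0) and Dppa4 hairpin (694, 1), H3K4me3 in recovery of the Dppa4 hairpin (145, 0), and H3K27me3 with the Dppa2 (479, 0) and Dppa4 hairpin (556, 0). For H3K4me3 in recovery of the Dppa2 hairpin (0, 0) and H3K27me3 in recovery of the Dppa2 (0, 1) and Dppa4 hairpin (0, 2) all 10 splits had as many. The day 9 split with 1543 calls put WT sets 1 and 3 with DKO set 1, and the 3 other splits that part as many pairs as the real one called 0.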
